A study of Homo sapiens with 4 samples.

How the data were processed

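Jurkat cells with a scrambled hairpin (sh-Scb, 2 libraries) or a hairpin against SOX4 (sh-SOX4, 2 libraries) were profiled by RNA-seq. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The deposited table holds whole-number counts per gene, not normalized, under Ensembl gene IDs, with a column per library. The submitters' processing notes name HISAT2 2.2.0, StringTie and hg38. The role of each tool, the annotation release, the use of strand and any filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The control columns carry the name NC in place of sh-Scb; they were taken as the scrambled-hairpin libraries because the other columns name SOX4, and their replicate numbers match.

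The table has 64252 gene IDs. A symbol was found for 56105 of them, holding 98.04% of counts, and 56591 are in GENCODE release 29 on GRCh38, the assembly that hg38 names, from which coordinates and exon overlaps were taken. IDs in neither source held 1.80% of counts. No row lacked a gene ID. The 4 libraries summed to between 29093287 and 36636219 counts, where 3 counts correspond to 0.0819 to 0.103 CPM. Intervals and floors cover counting error only, except the 95% interval of the SOX4 change, which comes from the model.

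Counts were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), scaled by TMM and fitted by group with edgeR's robust quasi-likelihood model in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the 19897 IDs tested, at a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.101, with 2 residual degrees of freedom. Nothing in the labels says that libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries of a group were compared first: the median chi-square per gene was 1.71 in sh-Scb and 1.60 in sh-SOX4, against 0.455 for sampling alone, so none was treated as a duplicate.

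Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, two-sided, where at least 5 members were measured, and adjusted over 27 lists. With an estimated correlation this test has 2 residual degrees of freedom. The design, the 31 gene lists, the rule for named genes and the other settings listed here, apart from those said to be added later, were fixed before the data were examined. The rule named SOX4, then the 10 largest rises and 10 largest falls with a symbol, an adjusted p under the threshold, a mean log2 CPM of at least 2 and groups that do not overlap, then the 3 members with the smallest adjusted p of each list that passed or had at least 4 calls. Other genes named in a list were chosen after their values were seen, as exceptions or because few were called. Some genes that the rule names are not reported here.

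Alternatives were median-ratio size factors, library totals, no filter, at least 10 CPM in 2 libraries, a replicate block, each library left out, thinning to 29093287 counts, IDs with a symbol only, DESeq2 1.42.0, limma-voom, a test against 1.2-fold, camera with an estimated correlation and fry. A correction for GC content and length, and leaving out genes with 90% or more of exonic bases shared, were added after seeing the data. The pipeline was tested on simulated counts for 2 against 2 libraries and 19897 IDs. It recovered 42.9% of 70 genes changed 1.5-fold, 75.7% of 70 changed 2-fold and 95.0% of 60 changed 4-fold. It called 12 of 19671 unchanged IDs. Far fewer IDs were changed there than the 44.1% called in the data, so these rates need not hold for this comparison. Figures were drawn with matplotlib 3.10.9.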

Results

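RNA-seq gene counts were compared between Jurkat cells, a human T cell acute lymphoblastic leukemia (T-ALL) line, carrying a scrambled short hairpin RNA (sh-Scb) and the same line carrying a hairpin against SOX4 (sh-SOX4). SOX4 is a transcription factor of the SOXC family that is needed in early lymphocyte development. Each group held 2 libraries. The sh-Scb libraries summed to 36636219 and 29093287 counts, and the sh-SOX4 libraries to 32872606 and 30830081. Means below are depth-scaled counts (CPM) with the SD over 2 libraries, and fold changes compare sh-SOX4 with sh-Scb.

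SOX4 itself (ENSG00000124766, chromosome 6, 21592768 to 21598619 on GRCh38) was lower in both sh-SOX4 libraries. It was counted 10246 and 8344 times in the sh-Scb libraries and 6049 and 5914 times in the sh-SOX4 libraries. The normalized level was 274 ± 4.26 CPM (SD, n = 2) in sh-Scb and 195 ± 5.61 CPM (SD, n = 2) in sh-SOX4. This left 71.1% of the control level, with a 95% interval of 66.4% to 76.1%. The log2 fold change was -0.49 with an SE of 0.044, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 1.24e-05. Among the called genes, 5113 changed by more than SOX4 in size. The position that the hairpin targets is not given in the sources used here. Of its SOXC relatives, SOX11 had a log2 fold change of -0.33 and SOX12 of 0.12, and neither passed the test.

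**Figure D1:**
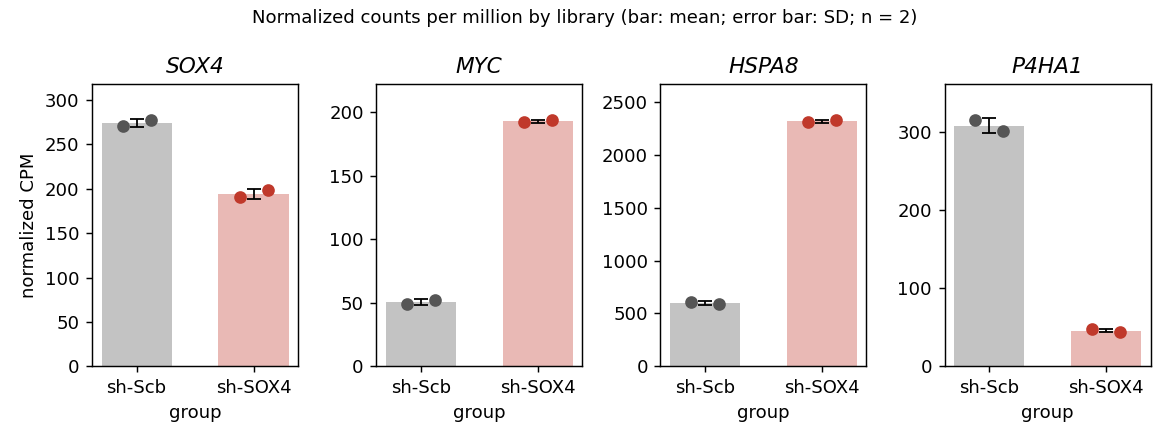
Normalized CPM of SOX4, MYC, HSPA8 and P4HA1 in each library; points are libraries, bars are group means and error bars are the SD (n = 2 per group). SOX4 stood at 274 CPM in sh-Scb and 195 CPM in sh-SOX4, while MYC rose from 50.7 to 193 CPM and P4HA1 fell from 308 to 45.6 CPM.

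The question of the comparison was which transcripts differ when SOX4 is reduced. Genes of ribosome biogenesis rose together in sh-SOX4, and MYC, the transcription factor known to drive many of them, rose 3.81-fold from 50.7 ± 2.07 to 193 ± 0.977 CPM (SD, n = 2). This list had a camera adjusted p = 0.114 with an estimated correlation. Genes of cholesterol and fatty acid synthesis fell almost throughout, led by LSS, the lanosterol synthase, from 351 ± 5.0 to 66.8 ± 6.97 CPM (SD, n = 2); camera gave an adjusted p = 0.0543 with an estimated correlation. Glycolytic and hypoxia-responsive genes fell too, among them P4HA1, a collagen prolyl hydroxylase subunit, from 308 ± 9.55 to 45.6 ± 2.19 CPM (SD, n = 2); camera gave an adjusted p = 0.117 with an estimated correlation. The chaperone HSPA8 rose 3.86-fold, from 599.9 ± 18.3 to 2318 ± 12.4 CPM (SD, n = 2).

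Of 19897 gene IDs tested, edgeR's quasi-likelihood test called 8775 at an adjusted p under 0.05, 4609 of them higher and 4166 lower in sh-SOX4. Calls with a log2 fold change of at least 1 in size were fewer, with 674 higher and 1207 lower. Higher calls made up 52.5% of all calls. With scaling to the library total alone, 3629 IDs were higher and 5260 lower, so that 40.8% of calls were higher. That scaling moved the median log2 fold change of all tested IDs from -0.01 to -0.109, and every change given here is relative to the normalization used.

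**Figure D2:**
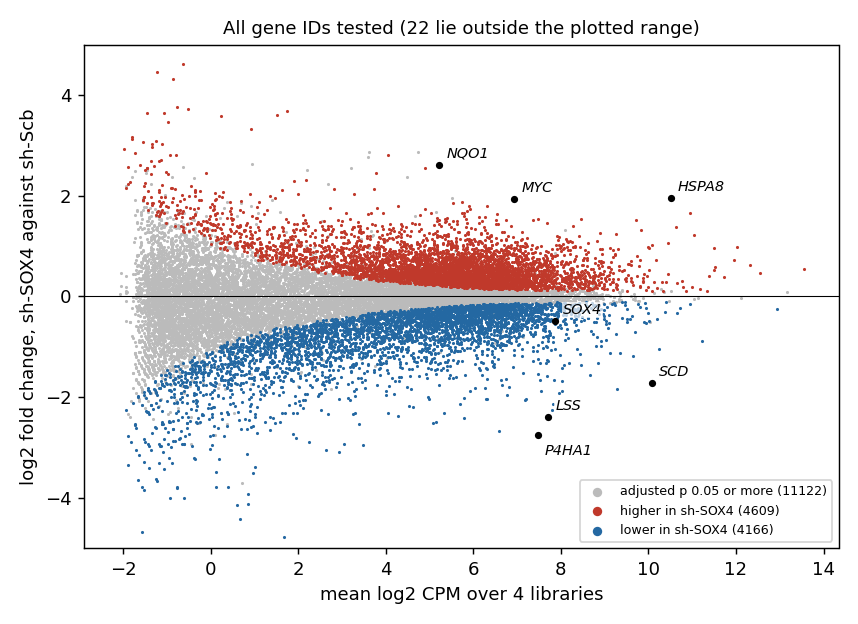
Log2 fold change (sh-SOX4 against sh-Scb) against mean log2 CPM for each gene ID tested; red points are the 4609 called higher, blue the 4166 called lower, and grey the rest. 22 IDs lie beyond the plotted range, and SOX4, labelled in black, lies closer to 0 than MYC, HSPA8, NQO1, SCD, LSS and P4HA1.

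The largest rise among well-expressed genes was that of NQO1, a quinone reductase (chromosome 16, 69706996 to 69726951), with a log2 fold change of 2.61 (SE 0.17). OSGIN1, an oxidative stress response gene, rose by 2.55 (SE 0.092). S100A9, a calcium-binding protein of myeloid cells, rose from 4.22 ± 0.573 to 23.2 ± 0.225 CPM (SD, n = 2). CTSG, the granule protease cathepsin G, rose from 20.1 ± 0.423 to 72.8 ± 5.03 CPM (SD, n = 2). RAET1E, a ligand of the NKG2D receptor, rose by 2.32 on the log2 scale, AVEN, a caspase inhibitor, by 2.13 and GPATCH4 by 1.88. POLR1G, an RNA polymerase I subunit, had a log2 fold change of 2.13, but 45.1% of its exonic bases also lie in other genes, ERCC1 and PPP1R13L among them. Adjusted p-values from edgeR's quasi-likelihood test for these 10 genes, MYC and HSPA8 included, ran from 3.73e-09 for HSPA8 to 0.00283 for POLR1G. HSPA8 has 17 annotated pseudogene copies that could take or give reads, so its level is uncertain. The same limit holds for other genes named below, among them ATP5PB with 8 copies, XRCC6 with 5 and RBPJ with 4.

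Among the falls that the naming rule admits, at a mean log2 CPM of at least 2, MIR210HG led with a log2 fold change of -3.08 (SE 0.20). It is the host transcript of a hypoxia-induced microRNA (chromosome 11, 565660 to 568457). L1CAM, a cell adhesion molecule, fell from 10.9 ± 1.25 to 1.31 ± 0.243 CPM (SD, n = 2). SCART1 fell by 2.95 on the log2 scale and ARHGEF40 by 2.93. The mitochondrial phenylalanine tRNA, MT-TF, fell by 2.88, although short RNAs are poorly captured in such libraries. PFKFB4, a regulator of glycolytic flux, fell from 165 ± 10.3 to 25.9 ± 1.5 CPM (SD, n = 2). PPFIA4 had a log2 fold change of -2.48 and YPEL1 of -2.51, with 52.4% of the exonic bases of YPEL1 shared, PPIL2 being the tested gene it overlaps. Adjusted p-values from edgeR's quasi-likelihood test for these falls and for P4HA1 and LSS were between 3.73e-09 and 3.82e-06.

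Of 31 gene lists fixed beforehand, 27 had enough measured members for a set test. Calls within a list are to be read against the 44.1% of all tested IDs that were called. With the filter of at least 10 CPM in 2 libraries, 7149 of 10797 IDs were called. With so many calls, adjusting over a list alone mostly returns the same members and is no separate evidence. Camera with a preset correlation and Benjamini-Hochberg adjustment called 6 lists higher and 5 lower. With the correlation estimated from the 4 libraries, camera called none, although 5 lists had an unadjusted p under 0.05, and the adjusted p under that setting stands beside each of the 11 lists called with the preset correlation.

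**Figure D3:**
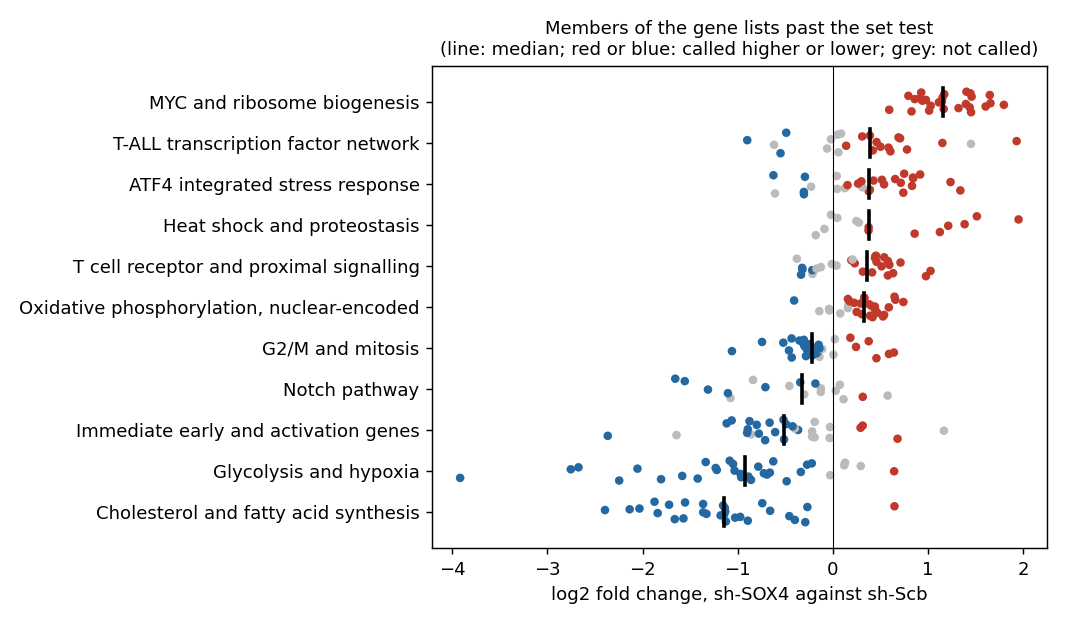
Log2 fold change (sh-SOX4 against sh-Scb) of each measured member of the 11 lists called by camera; each point is a gene, black lines are list medians, and red, blue and grey mark genes called higher, called lower and not called. The MYC and ribosome biogenesis list has a median of 1.16 and the cholesterol and fatty acid synthesis list of -1.15.

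All 26 measured genes of the MYC and ribosome biogenesis list rose, and 26 did so adjusted over the list alone. Their median log2 fold change was 1.16. NOLC1, a nucleolar phosphoprotein, rose from 171 ± 0.684 to 449.9 ± 4.46 CPM (SD, n = 2). NOP56, a core protein of box C/D ribonucleoproteins, rose by 1.14 (SE 0.043) and the mitochondrial chaperonin HSPD1 by 1.32 (SE 0.040) on the log2 scale. HSPD1 has 18 annotated pseudogene copies, so its level is uncertain. Camera gave an adjusted p of 1.31e-61 for the list, and an adjusted p = 0.114 with an estimated correlation.

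Of 28 genes of cholesterol and fatty acid synthesis, 27 fell and 1 rose, counts that were also 27 and 1 adjusted over the list alone. The riser was PMVK, phosphomevalonate kinase, with a log2 fold change of 0.65. SCD, the stearoyl-CoA desaturase, fell from 1668 ± 10.8 to 506 ± 2.04 CPM (SD, n = 2). MSMO1, a sterol demethylation enzyme, fell by 2.14 (SE 0.048) and MVD, the mevalonate diphosphate decarboxylase, by 2.03 (SE 0.047) on the log2 scale. The list median was -1.15, with a camera adjusted p of 1.36e-84, and an adjusted p = 0.0543 with an estimated correlation.

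In the glycolysis and hypoxia list, 27 of 32 genes fell and 1 rose, LDHB, a lactate dehydrogenase subunit, by 0.64 on the log2 scale. The other 4, SLC2A1, PFKP, PFKM and GAPDH, did not pass over all genes. Adjusted over the list alone, 27 fell and 2 rose. PDK1, a kinase that restrains pyruvate dehydrogenase, fell from 235 ± 2.02 to 56.6 ± 2.53 CPM (SD, n = 2), and P4HA1 and PFKFB4, given above, were the other genes with the smallest adjusted p. The median was -0.93, with a camera adjusted p of 7.16e-46, and an adjusted p = 0.117 with an estimated correlation. In the nuclear-encoded oxidative phosphorylation list, 21 of 28 genes rose and 1 fell, SDHA, with the same counts adjusted over the list alone. UQCRFS1 of complex III rose by 0.65 (SE 0.055), ATP5F1B of the ATP synthase by 0.53 (SE 0.046) and ATP5PB by 0.54 (SE 0.049). The median was 0.33, with a camera adjusted p of 6.91e-05, and an adjusted p = 0.507 with an estimated correlation. Beside this list, counts in mitochondrially encoded genes made up 4.78% ± 0.038 (SD, n = 2) of the sh-Scb libraries and 6.20% ± 0.042 (SD, n = 2) of the sh-SOX4 libraries. The share in mitochondrial mRNAs rose from 3.73% ± 0.066 to 5.36% ± 0.045 (SD, n = 2). That in mitochondrial rRNAs fell from 0.993% ± 0.03 to 0.808% ± 0.002 (SD, n = 2).

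Of 14 heat shock and proteostasis genes, 8 rose, also adjusted over the list alone. The other 6, HSPA1A, HSPA1B, HSPB1, BAG3, DNAJB4 and SQSTM1, did not pass. HSP90AB1, a constitutive cytosolic chaperone, rose from 877 ± 16.9 to 2287 ± 32.0 CPM and HSPH1, a nucleotide exchange factor for HSP70 proteins, from 85.4 ± 0.651 to 244 ± 9.43 CPM (SD, n = 2). The median was 0.37, with a camera adjusted p of 8.12e-16, and an adjusted p = 0.117 with an estimated correlation. In the ATF4 integrated stress response list, 18 of 28 genes rose and 4 fell, against 19 and 5 adjusted over the list alone. The amino acid transporter gene SLC7A5 rose by 0.84 (SE 0.041), the glycyl-tRNA synthetase GARS1 by 0.83 (SE 0.043) and the tRNA exporter XPOT by 0.75 (SE 0.042). Those that fell were VLDLR, ATF3, AARS1 and STC2. Camera gave an adjusted p of 2.39e-06, and an adjusted p = 0.171 with an estimated correlation. Of 17 genes of the unfolded protein response, 5 rose and 7 fell, with 5 and 7 also adjusted over the list alone, and the camera adjusted p was 0.693. HSPA5, the chaperone of the endoplasmic reticulum, rose by 0.48 (SE 0.039), while CALR fell by 0.44 (SE 0.036) and EDEM1 fell by 0.46 (SE 0.039).

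In the T-ALL transcription factor network, 13 of 23 genes rose and 3 fell, against 14 and 4 adjusted over the list alone. TAL1, a basic helix-loop-helix oncogene of T-ALL, rose from 225 ± 0.0960 to 363 ± 7.04 CPM (SD, n = 2). ARID5B and TRIB2 were among the genes that fell. The median was 0.39, with a camera adjusted p of 0.000857, and an adjusted p = 0.408 with an estimated correlation. Of 28 genes of the T cell receptor and its proximal signalling, 17 rose and 4 fell, against 17 and 6 adjusted over the list alone. CD3G, a receptor chain, rose by 1.02 (SE 0.059) and the phosphatase PTPN22 by 0.71 (SE 0.055). CD247, FYN, CD6 and CD5 fell. The median was 0.36, with a camera adjusted p of 0.000501, and an adjusted p = 0.23 with an estimated correlation. Thymocyte stage genes did not pass as a list, with a camera adjusted p of 0.162. Of 21 measured, 2 rose and 8 fell, with 2 and 8 also adjusted over the list alone. The recombinase gene RAG1 fell by 0.69 (SE 0.053), CD38 fell by 0.42 (SE 0.048) and KIT fell from 3.20 ± 0.112 to 0.537 ± 0.00103 CPM (SD, n = 2), while RAG2 and DNTT rose.

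Among immediate early and activation genes, 16 of 29 fell and 3 rose, with 16 and 3 adjusted over the list alone. EGR1, an early growth response factor, fell from 32.1 ± 0.709 to 6.23 ± 0.164 CPM (SD, n = 2). ETV5 fell by 0.90 (SE 0.043) and TNFAIP3 fell by 0.52 (SE 0.050), while DUSP2, NFKBIA and JUN rose. The median was -0.51, with a camera adjusted p of 0.00107, and an adjusted p = 0.316 with an estimated correlation. In the Notch pathway list, 7 of 18 genes fell and 1 rose, DTX1, with the same counts adjusted over the list alone. RBPJ, the DNA-binding partner of cleaved Notch, fell from 277 ± 4.34 to 88.0 ± 0.902 CPM (SD, n = 2). NOTCH3 fell by 1.56 (SE 0.11), and the growth factor receptor IGF1R fell by 1.31 (SE 0.080). HES1, a direct Notch target, had a log2 fold change of 0.57 and did not pass. The median was -0.32, with a camera adjusted p of 0.000377, and an adjusted p = 0.351 with an estimated correlation.

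Of 30 genes of G2/M and mitosis, 20 fell and 6 rose, as they did adjusted over the list alone. MKI67, a proliferation marker, fell from 1155 ± 13.1 to 805 ± 9.46 CPM (SD, n = 2). NUSAP1, with 62.2% of its exonic bases shared with other annotated genes, fell by 0.74 (SE 0.043). CDC20, an activator of the anaphase-promoting complex, rose by 0.64 (SE 0.047). The median was -0.22, with a camera adjusted p of 0.0103, and an adjusted p = 0.461 with an estimated correlation. Genes of G1/S and DNA replication went both ways, with 9 higher and 8 lower of 30, against 9 and 11 adjusted over the list alone, and a camera adjusted p of 0.726. CCNE2 fell by 1.09 (SE 0.068), with 37.1% of its exonic bases shared, and E2F2 fell by 0.62 (SE 0.053), while the kinase CDK6 rose by 0.65 (SE 0.049). Of 9 CDK inhibitor and pocket protein genes, 2 rose and 6 fell, as also adjusted over the list alone, with a camera adjusted p of 0.16. CDKN2D fell by 0.84 (SE 0.073) and RBL2 fell by 0.48 (SE 0.047), while RBL1 rose by 0.40 (SE 0.067).

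Genes of cell death and of the p53 response were mixed. Of 22 p53 target genes, 7 rose and 8 fell, against 8 and 8 adjusted over the list alone, with a camera adjusted p of 0.693. AEN, a nuclease, rose by 0.97 (SE 0.059), while TP53INP1 fell by 1.42 (SE 0.090) and DDB2 fell by 0.63 (SE 0.053). Of 22 pro-apoptotic genes, 11 rose and 6 fell, against 12 and 6 adjusted over the list alone, and camera gave an adjusted p of 0.546. BMF fell by 1.38 (SE 0.073) and APAF1 fell by 0.93 (SE 0.058), while BID rose by 0.79 (SE 0.064). Of 11 anti-apoptotic genes, BIRC6 rose and MCL1 and BIRC2 fell, 1 and 2 genes that were also called adjusted over the list alone, with a camera adjusted p of 0.686. In the DNA damage repair list, 9 of 27 genes rose and 10 fell, as also adjusted over the list alone, with a camera adjusted p of 0.929. Its median was -0.042 and its mean 0.008. XRCC6 rose by 0.59 (SE 0.039) and RAD51C by 0.75 (SE 0.081), while FANCI fell by 0.44 (SE 0.038).

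The Wnt, PI3K, TGF-beta, adhesion and interferon lists did not pass either. Of 24 Wnt and beta-catenin genes, 7 rose and 8 fell, also adjusted over the list alone, and camera gave an adjusted p of 0.988 with a direction opposite to the median of -0.008. APC rose by 0.42 (SE 0.058) and LRP5 by 0.48 (SE 0.094), while NKD2 fell by 0.81 (SE 0.11). Of 31 PI3K, AKT and FOXO genes, 6 rose and 6 fell, also adjusted over the list alone, with a camera adjusted p of 0.406. CCNG2, a FOXO target, fell by 2.03 (SE 0.070) and SESN3 fell by 1.28 (SE 0.11), while RPTOR, a subunit of the mTORC1 kinase complex, rose by 0.86 (SE 0.060). In the TGF-beta and mesenchymal list, 3 of 23 genes rose and 7 fell, as adjusted over the list alone, with a camera adjusted p of 0.142. SMAD3 fell by 0.93 (SE 0.083), TGFBR1 fell by 0.78 (SE 0.069) and EZH2 fell by 0.39 (SE 0.043), while FN1, SKIL and SMAD6 rose. Of 24 adhesion and migration receptors, 12 rose and 6 fell, against 12 and 7 adjusted over the list alone, with a camera adjusted p of 0.693. The integrin ITGA6 fell by 2.02 (SE 0.072) and CD47 fell by 0.56 (SE 0.039). Of 29 interferon response genes, 12 rose and 4 fell, against 12 and 5 adjusted over the list alone, with a camera adjusted p of 0.351. IRF1 rose by 0.59 (SE 0.046) and IFI44 by 1.47 (SE 0.21), while HERC5 fell by 0.66 (SE 0.085).

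Markers of other blood and tissue cells were read as levels. Of 8 measured myeloid markers, S100A8, S100A9 and AIF1 rose and CD68 fell, 3 and 1 genes that were also called adjusted over the list alone, with a camera adjusted p of 0.162. S100A8 had 0 counts in both sh-Scb libraries and 42 and 36 in the sh-SOX4 libraries, at least 26.8-fold higher against a floor of 3 counts over the group. CD68, with 85.8% of its exonic bases shared, had a log2 fold change of -0.75 and an edgeR adjusted p of 0.0297, which became 0.301 without sh-Scb replicate 2, 0.0545 without sh-SOX4 replicate 1 and 0.123 without sh-SOX4 replicate 2. Of 6 B cell markers, CD79B rose and CD79A and CD22 fell, 1 and 2 genes that were also called adjusted over the list alone, with a camera adjusted p of 0.0601 that became 0.0328 without sh-SOX4 replicate 1. CD79A went from 66.6 to 13.3 CPM. The other 2 had low counts. CD79B had 18 and 11 counts in the sh-Scb libraries and 67 and 27 in the sh-SOX4 libraries, which differed from each other. CD22 had 20 and 15 counts in sh-Scb and 0 and 1 in sh-SOX4. Of 6 NK and cytotoxic markers, PRF1 rose and GNLY and GZMA fell, 1 and 2 genes also adjusted over the list alone, with a camera adjusted p of 0.693. The measured erythroid markers HBA1, HBA2 and HBG2 and the epithelial markers KRT8 and CLDN4 did not pass, nor did they adjusted over the list alone. Of 3 fibroblast markers COL1A1 fell, the 1 gene also called adjusted over the list alone. These lists and the SOXC list, in which SOX4 was the 1 gene of 3 called over all genes and adjusted over the list alone, were too short for a set test.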

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

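The GC and length correction and the removal of overlapping genes were chosen after seeing the data. SOX4 stayed lower and past the threshold in all 15 alternative fits, between -0.46 and -0.53 on the log2 scale when a library was left out. No called ID changed direction in any alternative that called it too. Leaving out a library gave 3838 to 4483 IDs higher and 3629 to 3811 lower. With the replicate block, 4422 IDs were higher and 3956 lower and SOX4 stood at -0.49. Deviations of libraries with the same number correlated at -0.01 over all genes and at -0.47 over those at a log2 CPM of 5 or more. Nothing in the labels pairs these libraries. A block by number cannot take up a spread that runs opposite ways in the 2 groups, so it is a weak check for the well-expressed genes. Testing against 1.2-fold left 2757 higher and 2591 lower, and requiring a log2 fold change of 1 left 674 and 1207, both by construction. DESeq2 called 4048 and 3405, with 2315 adjusted p-values not given, and limma-voom 4659 and 4178. Camera with an estimated correlation called 0 lists higher and 0 lower, against 6 and 5 with the preset correlation. With the estimate the test has 2 residual degrees of freedom. In the cholesterol, T cell receptor and ATF4 lists the estimated correlation was -0.006, 0 and 0.003, below the preset 0.01. This argues against a higher correlation as the reason that these lists lost their calls. In the other called lists the estimate was above 0.01, and the cause was not tested. Of 6 lists added after seeing the data, 3 passed with an estimated correlation. They are no like comparison, being listed once other results were known and adjusted over 6 lists in place of 27. Fry, which tests a list on its own and not against other genes, called 10 higher and 11 lower. Named genes kept their calls in 1295 comparisons with an alternative; CD68 alone lost its call, in 4 settings, limma-voom (adjusted p 0.0556) and 3 with a library left out, over a range from 0.000272 to 0.301. The B cell list passed in fry and without sh-SOX4 replicate 1, with adjusted p-values from 0.0303 to 0.408 over the alternatives. Depth limits genes near the floor, such as S100A8.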

Other observations

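The gene groups in this paragraph were chosen after the data were seen, so their counts describe these libraries and are no independent evidence. Of 19 measured targets of the oxidative stress factor NRF2 and glutathione genes, 16 rose and 1 fell, PGD, with a median log2 fold change of 1.02. With an estimated correlation, camera gave an adjusted p of 0.0233 for this group over the 6 added groups it tested. Ferritin chains were among them: FTL went from 435 ± 16.9 to 1242 ± 17.8 CPM (SD, n = 2). TXNRD1, a thioredoxin reductase, went from 368 ± 9.75 to 866 ± 15.8 CPM (SD, n = 2). All 8 subunits of the cytosolic chaperonin rose, with a median of 0.98, as did 14 of 17 RNA polymerase I and III subunits. The polymerase group had a camera adjusted p of 0.0366 with an estimated correlation, the chaperonin group and the GIMAP family 0.0597, and the snoRNA host genes, of which 12 of 16 rose and 1 fell, 0.122. All 7 genes of the GIMAP family, small GTPases of lymphocytes, rose, and GIMAP5 rose from 26.0 ± 2.10 to 81.6 ± 3.01 CPM (SD, n = 2). Of 78 mitochondrial ribosomal protein genes, 73 rose and the other 5 did not pass, with a median of 0.61. Of 83 cytosolic ribosomal protein genes, 38 rose, 4 fell and 41 did not pass, with a median of 0.11. With library totals, 29 of them rose and 9 fell, with a median of 0.015. In that setting 68 mitochondrial ribosomal protein genes rose and 1 fell, with a median of 0.507. The difference between these groups was not tested. Ribosomal protein genes made up 4.625% and 4.264% of counts in sh-Scb replicates 1 and 2, against 4.623% and 4.659% in sh-SOX4. On this share sh-Scb replicate 1 lay within the range of the sh-SOX4 libraries. The small rise of cytosolic ribosomal protein genes may therefore lean on sh-Scb replicate 2. Mitochondrially encoded mRNAs rose in 12 of 13 cases, while 9 of 22 mitochondrial tRNAs fell and 1 rose.

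In the paragraphs below, the tests of library scaling, of counting noise, of opposite differences in overlapping genes and of myeloid markers low in sh-Scb were chosen after the result was seen. The sterol, glycolysis and MYC lists moved by medians of over 0.9 in size. The tables argue against scaling as the whole cause, because the lists moved in opposite directions: under the single factor that suits them best, the largest of the 3 medians would still be 1.153 in size. After the GC and length correction the smallest list median was 0.932 in size. A difference in state between the cultures of the arms, such as density or medium, cannot be told apart from an effect of the hairpin. Libraries of an arm differed by at most 0.055 along these lists, which is what both would give if each arm was a single culture, and SOX4 fell by only 28.9%. An effect of SOX4 itself stays open as the biological explanation, and an effect of the hairpin on other transcripts was not tested.

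Some gene IDs with sizeable counts differed by over 8-fold between libraries of the same group. There were 46 such cases over 43 IDs. BEST1, which overlaps the ferritin gene FTH1, had 3361 and 57 counts in the sh-SOX4 libraries. The median of the higher count was 206.5, which decides nothing on counting noise, since the IDs were picked above 2 CPM. In 34 cases with an overlapping gene, summing both brought the median log2 ratio from 3.98 to 0.077, but this decides nothing, since it would be 0.126 with the overlapping genes held constant. The overlapping genes differed the opposite way in 29 of the 34 cases (exact binomial test, two-sided, p = 3.86e-05). Their difference had a median of 0.826 of that in the ID itself (quartiles 0.191 and 1.24). Some IDs enter in both groups, so the cases are not all independent. In only 6 cases were the overlapping genes at most 3 times as abundant. Of these, 5 went the opposite way (exact binomial test, two-sided, p = 0.219). Among annotated IDs, 25 of 33 shared at least 90% of their exonic bases against 204 of 18516 others (Fisher's exact test, two-sided, p = 6.46e-42). Reads moved between overlapping gene models may account for many of the 34 cases; of the rest, 2 share no exonic base in GENCODE release 29 and 10 have no entry there, and no biological explanation was tested.

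S100A8, S100A9 and CTSG were higher in sh-SOX4, which a few myeloid cells in those cultures could give. In this paragraph all CPM are of the library total, unlike the normalized CPM given for S100A9 and CTSG above. The test set beforehand summed LYZ, TYROBP, AIF1 and CD14, and did not decide: the sum was 11.85 CPM in sh-SOX4, against a rise of 18.1 CPM for S100A9. Its bound was badly chosen, because these genes already summed to 9.58 CPM in sh-Scb, 9.40 of it AIF1. A later test used LYZ, TYROBP, MPO, ELANE, PRTN3 and AZU1, which together stood at 0.541 CPM in sh-Scb and 0.516 CPM in sh-SOX4, or 2.86% of the S100A9 rise. LYZ, among the most abundant transcripts of myeloid cells, had 0 counts in all 4 libraries, and CTSG stood at 20.8 CPM of the library total in sh-Scb already. These values argue against myeloid cells as the source, on a marker set picked after the levels were known; a change within the Jurkat cells stays open and untested.

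A hypothesis for the fall of sterol genes was that sh-SOX4 cells were replete with sterol, which would also induce targets of the LXR receptors. Of ABCA1, ABCG1 and MYLIP, 0 were called higher, and they fell by 0.63, fell by 0.69 and fell by 0.86 on the log2 scale. This argues against an induction of these LXR targets in sh-SOX4. A further gene of that group, NR1H3, which encodes an LXR receptor, went the other way and rose by 0.52 (edgeR adjusted p 0.0171). Sterol repletion without LXR induction was not tested. Another hypothesis was that the fall of glycolytic genes was part of a lower oxygen-sensing (HIF) programme. The 14 oxygen-responsive genes outside glycolysis, listed after the glycolysis result but before their own values were seen, had a median log2 fold change of -1.324 and 14 were called lower (camera adjusted p = 0.0233 with an estimated correlation), among them AK4, GBE1 and WSB1. The fixed glycolysis and hypoxia list already held genes of this kind that fell, such as BNIP3, NDRG1 and VEGFA. A fall of the 14 genes was therefore likely in advance, and is no separate test of a HIF programme. The values could go with lower HIF activity in the sh-SOX4 cultures, which could equally reflect a different oxygen supply or density of the cultures.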
